A study of Homo sapiens with 4 samples.

How the data were processed

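Polysomal RNA of 2 cultures was measured on 4 one-colour oligonucleotide arrays, 2 for Huh7.5 and 2 for Huh7.5M. The labels describe both cultures as human hepatoma. Per the labels' protocols, cells at up to 80% confluence were washed with cycloheximide (100 µg per ml), which holds ribosomes on their messages. Lysate holding 175 µg of RNA was run through a 10% to 50% sucrose gradient, and the polysomal fractions were pooled and purified. A 500 ng portion of RNA per sample was then copied from an oligo(dT) primer and transcribed into Cy3-labelled cRNA. The priming favours polyadenylated RNA. The labels give a replicate number for each array but do not state whether the replicates were grown as separate cultures, so the p-values measure the spread between these samples only, which may be technical.

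Scanner intensity values were read with Agilent Feature Extraction 11.5.1.1, per the file headers, which also record background subtraction, spatial and multiplicative detrending, and surrogate values for low signals within each array. The values deposited per spot are therefore processed intensities that are not yet scaled between arrays. The authors also deposited a table of log2 values with 1 row per probe. Set against the scanner files, each of its columns followed the log2 processed signal with r = 1.00 after rounding, and at least 99.7% of probes lay within 0.01 log2 units of a constant offset. Its columns had medians of -3.54, -3.64, -3.66 and -3.70 and a 75th percentile near 0, so the scale is log2, each array was shifted to its 75th percentile, and genes were not centred. This table served as an alternative only.

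Each array held 52857 spots, of which 1319 were controls. The other 51538 spots belonged to 50238 probes. Between 44 and 56 spots per array carried an outlier flag and were left out, and 0 spots were saturated. In Huh7.5 replicates 1 and 2, 66.4% and 59.6% of non-control spots were well above background, and in Huh7.5M replicates 1 and 2 the shares were 64.1% and 56.8%. The 75th percentile of the processed signal was 826 and 553 intensity units in Huh7.5 and 1173 and 642 in Huh7.5M. The header's median coefficient of variation among replicate spots was 4.40% and 3.53% on the arrays with replicate number 1 but 17.5% and 24.2% on those with number 2. The number of arrays limits the precision.

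The main values were log2 of the processed signal minus each array's 75th percentile over non-control probes. Spots of a probe were averaged, probes were kept when well above background on at least 2 of the 4 arrays, and a gene took its probe with the highest mean over all 4 arrays. Probes were named through a RefSeq gene table of assembly GRCh38.p14. An accession matched for 28595 probes, the symbol for 2998 and a synonym for 1176, while 17469 probes kept the name in the file. The array's own coordinates are on an older build, so no coordinates are given. In all 21982 genes were tested, 15368 of them named through the reference. Of 1163 called genes with several measured probes, 1086 had all probes pointing the same way, and 1 had called probes of opposite direction. Genes with near-identical relatives, among them the MAGEA, HLA, IFITM, histone, ORM, AKR1C and CYP3A families, may share signal on these probes.

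The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Differences are Huh7.5M minus Huh7.5 on the log2 scale, with the standard error (SE) of the fit. Where a gene's probe was not well above background on either array of a line, the fold is a lower bound. It sets the mean of the brighter line against the mean, per array, of the dimmer probe's value or the lowest signal well above background on that array, whichever was higher. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 arrays. It could then hardly call any list, so its high p-values decide nothing either way. The design held 38 lists of pathways, complexes and cell type markers, chosen with the tests before the data were examined. Of these, 37 had at least 5 tested members, and the list of mitochondrially encoded genes had 0 genes on the array. Counts within a list are given over all genes tested and adjusted over the list alone.

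The genes named in the text followed a rule. It took the 12 largest called rises and falls among genes with an official symbol, with non-overlapping lines and a signal well above background in at least 1 array of each line. It added the 5 genes per direction with the highest lower-bound fold, and from each list up to 4 members with the smallest p. Some genes that met the rule are not reported here. ACTB, GAPDH, CD81, SCARB1, OCLN and HNF4A, and list members named to complete a count, were chosen after their values were seen.

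Both arrays with replicate number 1 were on slide 1, scanned together, and both with number 2 were on slide 2, so the slide holds 1 array of each line. Deviations of same-numbered arrays from their line means correlated with r = 0.524 across genes. The slide entered as a replicate block in an alternative. Other alternatives were normexp background correction (offset 50), quantile and median scaling, no filter on dim probes, a filter requiring all 4 arrays, a trend and robust prior, the mean of a gene's probes, the authors' table, treat with a fold of 1.2, camera on ranks, and leaving out each array. Scaling on the spike-in controls together with the replicate block was added after seeing the data. Relative to the 75th percentile, the log2 spike-in signal was 3.30 (Huh7.5) and 2.05 (Huh7.5M) on slide 1. On slide 2 it was 0.71 and -0.02, so it moved more between slides than between lines.

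The test was tried on simulated data with the spread of these arrays, 21982 genes and 5 runs. It called 0 of 250 genes changed by a log2 difference of 1, 0 of 250 changed by 2, 14.0% of 250 changed by 4 and 95.2% of 250 changed by 8, with 18 false calls over the 5 runs and 0 lists called. Those simulations changed few genes, which makes the adjusted threshold stricter than in the real comparison. Their noise was drawn independently for each gene and array, without correlation between genes or a shared slide. The absence of called lists therefore does not measure how often camera calls lists falsely in the real data. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.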

Results

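The series measured which messenger RNAs were carried on polysomes, the clusters of ribosomes that translate a message, in a pair of cultures. The labels describe both cultures as human hepatoma. RNA of another cultured line on the Huh7.5M arrays stays open as a hypothesis, as set out below. Huh7.5 is a subline of the Huh7 liver carcinoma line that is widely used to grow hepatitis C virus. The labels describe Huh7.5 as sensitive and Huh7.5M as resistant to geneticin, an aminoglycoside that blocks protein synthesis. Each line had 2 arrays, so n = 2 against 2 throughout. Between 56.8% and 66.4% of the non-control spots of an array were well above background. Across the 21982 tested genes, the arrays of Huh7.5 correlated with each other at r = 0.956 and those of Huh7.5M at r = 0.949, while arrays of different lines correlated at 0.737 to 0.774. These correlations are across genes, which are not independent replicates.

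The comparison asked which messages differed on polysomes between the resistant and the sensitive culture. All 4 samples were polysomal RNA, so a difference in message amount cannot be told from one in ribosome loading. Messages of secreted liver proteins fell the most in Huh7.5M, and the cancer-testis antigens MAGEA2B and MAGEA3 and the protease inhibitor SPINT2 were among those that rose the most. Of 21982 tested genes, 3948 passed the adjusted threshold, 2149 higher and 1799 lower in Huh7.5M. The smallest called difference was 1.74 on the log2 scale. Of the genes called higher, 934 had no probe well above background on a Huh7.5 array, and of those called lower, 775 had none on a Huh7.5M array. Among called genes well above background on all 4 arrays, 869 were higher and 786 lower.

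**Figure D1:**
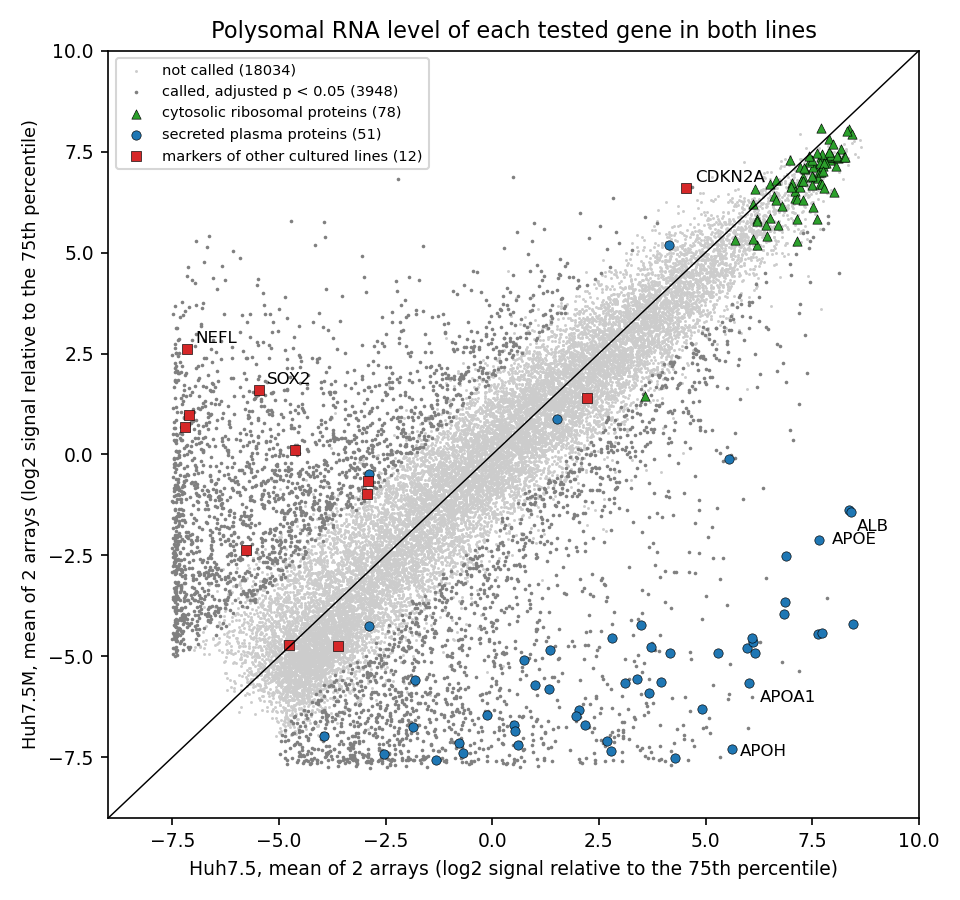
Each point is 1 of 21982 tested genes, placed by its mean of 2 arrays in Huh7.5 (x axis) and Huh7.5M (y axis), both as log2 signal relative to the array's 75th percentile; the line marks equal levels. Of the 51 secreted plasma proteins 46 were called lower in Huh7.5M, of the 12 markers of other cultured lines 7 were called higher, and the 78 ribosomal protein genes lie near the line.

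The largest falls were mostly in genes of hepatocyte products. AMBP, the precursor of alpha-1-microglobulin and bikunin, fell by 12.66 ± 1.63 (SE) on the log2 scale. SPINK1, a trypsin inhibitor, fell by 12.55 ± 1.18 and RBP4, the plasma carrier of retinol, fell by 12.16 ± 0.85. The apolipoproteins APOA2 and APOA1 showed differences of -12.09 ± 0.87 and -11.70 ± 0.93. TTR, the thyroxine carrier transthyretin, fell by 11.06 ± 1.04. ASGR2, a subunit of the asialoglycoprotein receptor, fell by 11.95 ± 0.67, and FABP1, the liver fatty acid binding protein, fell by 11.41 ± 0.80. ORM2, an acute-phase glycoprotein with a near-identical relative, fell by 10.92 ± 0.53. Outside the liver-specific genes, SCGN, a calcium-binding protein of neuroendocrine cells, fell by 12.10 ± 0.87. TGFBI, an extracellular matrix protein, fell by 11.59 ± 1.00. All 11 had an adjusted p of at most 0.00406, and all except FABP1 were well above background on only 1 of the 2 Huh7.5M arrays, so the sizes rest in part on values at background. With each value under an array's lowest signal well above background raised to it, the differences ran from -11.99 (RBP4) to -10.57 (TGFBI), with AMBP at -11.87. A further 5 were not well above background on either Huh7.5M array and were at least 2731-fold (FGL1), 2110.0-fold (APOH), 1733-fold (TM4SF4), 1488-fold (CPB2) and 1452-fold (ARG1) lower there.

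Of 51 tested genes for hepatocyte secreted plasma proteins, 46 fell and 0 rose, and adjusted over the list alone, as with the replicate block for the slide, 48 fell and 1 rose. ALB, the message of albumin, fell by 9.73 ± 0.50, AGT (angiotensinogen) fell by 10.78 ± 0.49 and ORM1 fell by 10.50 ± 0.54. Complement C3 was at least 545-fold lower. The list's median was -8.77, or -8.12 with dim genes at their bound, and it was -7.97 on slide 1 and -8.75 on slide 2. Camera called the list lower (adjusted p = 8.99e-28, and adjusted p = 0.375 with an estimated correlation). On the same Huh7.5M arrays, 7 of 12 tested markers of other cultured lines were called higher, with a list median of 2.83.

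Hepatocyte transcription factors were lower too, on the arrays where 7 of 12 markers of other cultured lines rose (median 2.83). Of 25 tested, 13 fell and 0 rose, and 17 fell adjusted over the list alone. NR1H4, the bile acid receptor, was at least 664-fold lower, and NR0B2, its target corepressor, fell by 6.61 ± 0.49. HNF4A, a central regulator of liver genes, had a difference of -2.31 ± 0.62 (adjusted p = 0.0551), which did not pass. HNF4A passed with the replicate block (adjusted p = 0.0131) and with the block and spike-in scaling together (-1.32, adjusted p = 0.0482). Its fall was smaller and did not pass with normexp (-1.02, adjusted p = 0.259) or with the mean of its probes (-1.19, adjusted p = 0.13). The difference was -3.03 without Huh7.5M replicate 2 and -1.60 without Huh7.5M replicate 1. The list's median was -2.53, with -3.03 on slide 1 and -2.04 on slide 2 (camera, adjusted p = 1.99e-08, and adjusted p = 0.375 with an estimated correlation). Of 16 tested cholangiocyte and progenitor markers, 14 fell and 1 rose, the same numbers as adjusted over the list alone. AFP, the fetal counterpart of albumin, fell by 10.76 ± 0.59, and CD24, a surface glycoprotein, fell by 7.10 ± 0.52. PROM1, a stem cell surface protein, was at least 152-fold lower. The member that rose was KIT, a receptor tyrosine kinase, at least 31.4-fold. That list's median was -5.02, or -4.24 with bounds, -5.56 on slide 1 and -5.03 on slide 2 (camera, adjusted p = 1.31e-07, and adjusted p = 0.375 with an estimated correlation).

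**Figure D2:**
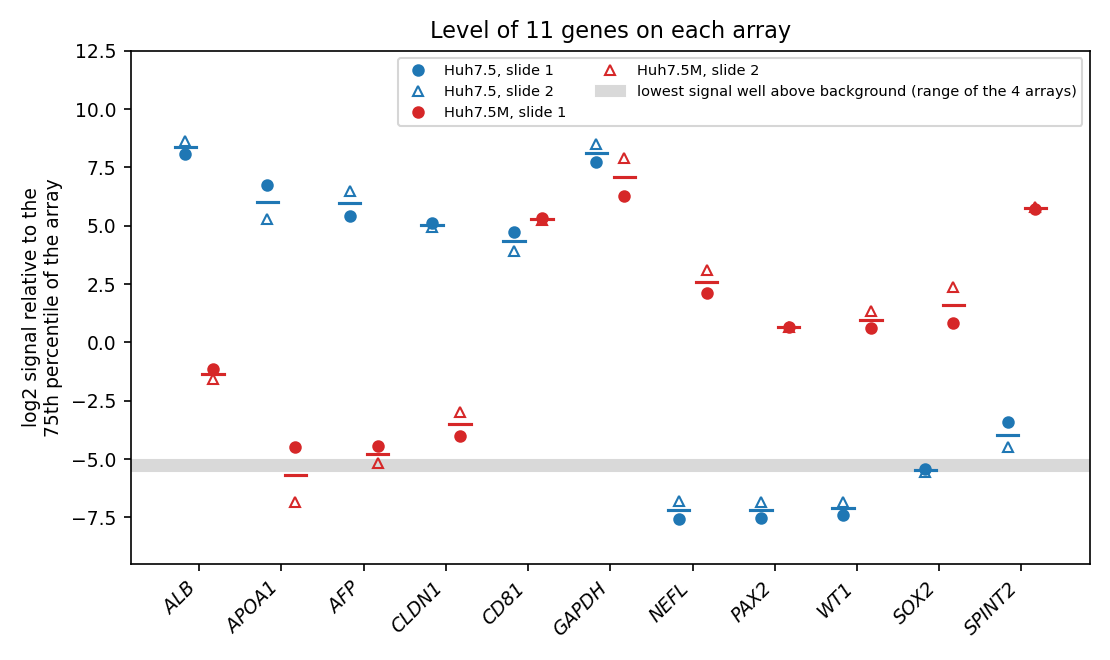
Level of 11 genes on each of the 4 arrays, as log2 signal relative to the array's 75th percentile; points are single arrays, short bars are means of 2, and the grey band spans the lowest signal well above background on the arrays. ALB stood at 8.10 and 8.63 in Huh7.5 against -1.16 and -1.59 in Huh7.5M, while NEFL stood at -7.55 and -6.79 against 2.10 and 3.10.

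Lists of liver metabolism were lower as well, on the same arrays where 7 of 12 markers of other cultured lines rose (median 2.83). Of 45 tested genes of xenobiotic metabolism, 22 fell and 1 rose, and adjusted over the list alone, as with the block, 25 fell and 2 rose. CYP4F12, a cytochrome P450, was at least 14.6-fold lower, the glutathione transferase GSTA2 at least 80.3-fold, the glucuronosyltransferase UGT2B7 at least 23.3-fold and the sulfotransferase SULT2A1 at least 275-fold. The list's median was -3.27, or -2.03 with bounds, -1.99 on slide 1 and -2.51 on slide 2 (camera, adjusted p = 3.27e-07, and adjusted p = 0.375 with an estimated correlation). It was -1.48 with normexp, -1.90 with no filter on dim probes and -0.79 where probes had to be well above background on all 4 arrays (adjusted p = 0.0466). Of 20 genes of bile acid metabolism and transport, 11 fell and 1 rose, against 12 and 1 adjusted over the list alone and 13 and 2 with the block. SLC51B, a subunit of the basolateral bile acid exporter, fell by 8.99 ± 0.48, and ABCC2, the canalicular conjugate exporter, fell by 6.52 ± 0.70. SLCO2B1 and SLCO1B3, uptake carriers, were at least 112-fold and 113-fold lower. SLC27A5, a bile acid coenzyme A ligase, was the member that rose (3.02 ± 0.49). This list's median was -3.68, or -2.85 with bounds, -3.32 on slide 1 and -3.74 on slide 2 (camera, adjusted p = 2.28e-05, and adjusted p = 0.375 with an estimated correlation). With normexp it was -1.53, with no filter -1.77 and on probes well above background on all 4 arrays -1.56 (adjusted p = 0.0267).

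Lists of lipid synthesis had smaller falls in the main setting, but no test compared lists. The xenobiotic and bile acid medians came down to -1.48 and -1.53 with normexp. Of 26 cholesterol synthesis genes, 6 fell and 0 rose, the same numbers as adjusted over the list alone, and 14 fell with the block. MVD and MSMO1, enzymes of the pathway, showed differences of -2.48 ± 0.51 and -3.45 ± 0.77, both called. Leaving out Huh7.5 replicate 1 ended the call of MVD (-2.10, adjusted p = 0.0970), and leaving out Huh7.5 replicate 2 ended that of MSMO1 (-2.42, adjusted p = 0.0683). The median was -1.51, with -1.45 on slide 1 and -1.56 on slide 2 (camera, adjusted p = 2.43e-04, and adjusted p = 0.609 with an estimated correlation). Of 29 genes of fatty acid and triglyceride synthesis, 8 fell and 0 rose, and 11 fell adjusted over the list alone and 16 with the block. MTTP, which loads lipid onto apolipoprotein B, fell by 9.11 ± 0.85, FADS2, a fatty acid desaturase, fell by 5.09 ± 0.77 and LPIN2, a phosphatidate phosphatase, fell by 3.09 ± 0.60. The call of LPIN2 ended without Huh7.5 replicate 2 (-2.44, adjusted p = 0.0638). CIDEB, a lipid droplet protein, was at least 29.6-fold lower. Its median was -1.63, with -1.40 on slide 1 and -1.64 on slide 2 (camera, adjusted p = 2.85e-04, and adjusted p = 0.548 with an estimated correlation). These falls stood beside the rise of 7 of 12 markers of other cultured lines (median 2.83) on the same arrays.

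Hepatitis C virus entry factors were lower as a list. Of 25 tested, 11 fell and 1 rose, against 14 and 1 adjusted over the list alone and 15 and 2 with the block. CLDN1, the tight junction protein used as an entry factor, fell by 8.53 ± 0.55, ASGR2 fell by 11.95 ± 0.67 and ASGR1 fell by 5.36 ± 0.48, and CLDN6 was at least 42.1-fold lower. CDHR1, a cadherin of photoreceptors, was the member that rose, at least 2.14-fold. The entry factors CD81, SCARB1 and OCLN did not pass. CD81 differed by 0.95 ± 0.51 (adjusted p = 0.270), SCARB1 by -1.74 ± 0.47 (adjusted p = 0.0548) and OCLN by -0.33 ± 0.54 (adjusted p = 0.721). SCARB1 passed with normexp (-1.68, adjusted p = 0.0459), with a trend and robust prior (adjusted p = 0.0228) and with the replicate block (adjusted p = 0.0204). With the block and spike-in scaling together, CD81 passed at 1.94 (adjusted p = 0.00893) and OCLN turned to 0.66. SCARB1 did not pass there (-0.75, adjusted p = 0.253). The list's median was -1.76, with -1.77 on slide 1 and -2.04 on slide 2 (camera, adjusted p = 1.66e-04, and adjusted p = 0.375 with an estimated correlation). Of 39 factors of viral replication and assembly, 6 fell and 2 rose, the same numbers as adjusted over the list alone, against 12 and 3 with the block. APOE fell by 9.78 ± 0.50, MTTP fell by 9.11 ± 0.85, CHKA, a choline kinase, fell by 3.95 ± 0.54 and APOB fell by 6.19 ± 1.00. The call of APOB ended with normexp (adjusted p = 0.0566, against 1.24e-04 to 0.0566 over its 13 alternatives). That list was not called (median -0.62, camera adjusted p = 0.119). It was called lower without Huh7.5 replicate 1 (-0.68, adjusted p = 0.0423) and without Huh7.5M replicate 2 (-0.98, adjusted p = 0.0104), and its median turned to 0.37 under spike-in scaling. The arrays on which the entry factors fell were those on which 7 of 12 markers of other cultured lines rose (median 2.83).

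The largest rises were in genes of varied function. MAGEA2B and MAGEA3, cancer-testis antigens with near-identical relatives, rose by 11.12 ± 0.88 and 10.49 ± 0.98. HOXB9, a homeobox gene of body patterning, rose by 9.32 ± 0.47. SPINT2, a Kunitz-type protease inhibitor, rose by 9.71 ± 0.55, PRKCZ, an atypical protein kinase C, by 9.33 ± 0.48 and LDHB, the heart-type subunit of lactate dehydrogenase, by 9.01 ± 0.77. BEX5 rose by 9.84 ± 1.03, TMSB15A, a thymosin beta, by 9.37 ± 1.24 and PJA1, a ubiquitin ligase, by 8.75 ± 1.18. TNNT1, the slow muscle troponin T, rose by 8.70 ± 0.56, VASH1, a vasohibin, by 8.60 ± 0.47 and TIMP1, an inhibitor of metalloproteinases, by 8.41 ± 0.57. SPINT2, PRKCZ, HOXB9 and LDHB were well above background on both Huh7.5 arrays and the other 8 on 1 of them. With values raised to the background limit as above, the rises ran from 7.70 (TIMP1) to 10.21 (MAGEA3), with MAGEA2B at 9.98. The lower-bound folds were at least 1276 for NMU (neuromedin U), 1001 for IFITM1 and 922 for PFKP, the platelet-type phosphofructokinase. For HOXB6 and MAGED1, the brightest probes were at least 1417-fold and 1057-fold higher, although another probe of each was well above background in Huh7.5. The HOXB6 probe well above background on all 4 arrays gave 2.95 and did not pass (adjusted p = 0.134).

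A list of genes abundant in other commonly cultured lines, such as HEK293 and HeLa, was higher. Of 12 tested, 7 rose and 0 fell, and 9 rose adjusted over the list alone. NEFL, the light neurofilament chain, was at least 221-fold higher, and the developmental transcription factors PAX2 and WT1 at least 58.0-fold and 72.0-fold. SOX2 was at least 111-fold higher on a probe not well above background in Huh7.5, where another of its probes was so on 1 array. NEFM, LHX1 and CDKN2A also rose, by 4.73 ± 0.59, 2.25 ± 0.53 and 2.04 ± 0.53, and the probes of NEFM disagreed in direction. In Huh7.5, 5 of the 12 were well above background on both arrays, and 0 belonged to another list. The median was 2.83, with 2.52 on slide 1 and 3.54 on slide 2 (camera, adjusted p = 5.83e-05, and adjusted p = 0.392 with an estimated correlation).

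Genes of antigen presentation were higher. Of 20 tested, 9 rose and 0 fell, the same numbers as adjusted over the list alone, against 10 and 2 with the block. TAP1, a subunit of the peptide transporter, was at least 388-fold higher, and the peptidase ERAP2 rose by 6.68 ± 0.57. HLA-F and HLA-B, members of a family with shared sequence, rose by 6.97 ± 0.64 and 4.36 ± 0.58. The list's median was 1.35, or 1.19 with bounds, 1.24 on slide 1 and 1.45 on slide 2 (camera, adjusted p = 0.00404, and adjusted p = 0.548 with an estimated correlation). It was smaller with normexp (0.72), with no filter on dim probes (0.16) and on probes well above background on all 4 arrays (0.28), and larger under spike-in scaling (2.33). Interferon-stimulated genes moved in both directions. Of 55 tested, 14 rose and 4 fell, against 15 and 5 adjusted over the list alone and 20 and 9 with the block. IFITM1, a membrane protein that restricts virus entry, was at least 1001-fold higher. MX2 and PARP12 were at least 653-fold and 30.4-fold lower. HERC6 was at least 12.1-fold higher, a call that normexp ended (adjusted p = 0.0520, against 2.37e-05 to 0.0520 over its 13 alternatives). The median was 0.39, with 0.35 on slide 1 and 0.27 on slide 2 (camera, adjusted p = 0.0388, and adjusted p = 0.598 with an estimated correlation). Camera's call on this list held in 7 of 13 alternatives, with adjusted p from 0.00848 to 0.207, and ended without Huh7.5 replicate 1 (0.148) and without Huh7.5M replicate 2 (0.162). The median was 0.16 with normexp, 0.18 on probes well above background on all 4 arrays, 0.68 without Huh7.5 replicate 2 and 1.38 under spike-in scaling. Both lists moved on arrays where the plasma protein list had a median of -8.77.

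Epithelial junction genes were lower, while mesenchymal genes went both ways. Of 31 junction genes, 13 fell and 1 rose, and 14 fell and 1 rose adjusted over the list alone. CLDN1 fell by 8.53 ± 0.55, ESRP2, an epithelial splicing regulator, fell by 6.76 ± 0.48 and MARVELD2 (tricellulin) fell by 7.22 ± 0.54, and SPINT2 was the one that rose. The list's median was -1.78, with -2.31 on slide 1 and -1.81 on slide 2 (camera, adjusted p = 6.32e-05, and adjusted p = 0.548 with an estimated correlation). Of 38 genes of the epithelial-mesenchymal transition, 11 rose and 5 fell, against 11 and 10 adjusted over the list alone and 14 and 12 with the block. The transcription factors SNAI2, TWIST1 and ZEB2 were at least 333-fold, 101-fold and 59.2-fold higher, while TGFBI fell by 11.59 ± 1.00. That list was not called (median 0.064, camera adjusted p = 0.628), and its median turned to -0.16 with normexp. These lists were read on arrays where the plasma protein median was -8.77 and that of the markers of other cultured lines was 2.83.

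The lists of the NRF2 response and of drug efflux transporters were lower too. The same arrays showed the rise of 7 of 12 markers of other cultured lines (median 2.83). Of 32 genes of the NRF2 oxidative stress response, 11 fell and 1 rose, against 15 and 1 adjusted over the list alone and 18 and 4 with the block. AKR1C3, a steroid reductase, was at least 16.8-fold lower and GPX2, a gut-type glutathione peroxidase, at least 24.8-fold. ABCC2 fell by 6.52 ± 0.70 and FTL, the ferritin light chain, fell by 2.99 ± 0.46, while AKR1B1, aldose reductase, rose by 2.84 ± 0.48. The median was -1.46, with -1.57 on slide 1 and -1.52 on slide 2 (camera, adjusted p = 0.00482, and adjusted p = 0.375 with an estimated correlation). The call ended when probes had to be well above background on all 4 arrays (median -0.83, adjusted p = 0.0524, against 5.30e-04 to 0.0524 over its 13 alternatives). Of 14 drug efflux transporters, 5 fell and 1 rose, against 6 and 1 adjusted over the list alone. Of the 14, 7 belonged to another list. ABCB1, ABCC2, ABCC3 and ABCG2, all called lower, were also counted under bile acid transport, so this is in part the same result. ABCA1, ABCC2 and ABCG2 showed called differences of -5.87 ± 0.55, -6.52 ± 0.70 and -3.93 ± 0.61, and ABCA3, a lipid transporter of the lung, was at least 114-fold higher. The median was -1.21, with -1.13 on slide 1 and -1.44 on slide 2 (camera, adjusted p = 0.0350, and adjusted p = 0.548 with an estimated correlation).

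Of 23 NF-kB and inflammatory genes, 3 fell and 0 rose, the same numbers as adjusted over the list alone, against 10 and 1 with the block. The chemokine CCL20 was at least 426-fold lower, the adhesion molecule ICAM1 at least 74.1-fold, and CXCL5 fell by 7.12 ± 0.97. The median was -1.46, with -1.79 on slide 1 and -1.01 on slide 2 (camera, adjusted p = 0.00333, and adjusted p = 0.548 with an estimated correlation), and -0.84 without Huh7.5 replicate 1 (adjusted p = 0.0367). Of 11 leukocyte and macrophage markers, 5 fell and 0 rose, and 6 fell adjusted over the list alone. LYZ (lysozyme) was at least 562-fold lower and PTPRC at least 15.6-fold. The median was -1.86, or -1.05 with bounds, -1.82 on slide 1 and -2.60 on slide 2 (camera, adjusted p = 0.00361, and adjusted p = 0.375 with an estimated correlation), -0.68 with normexp and -0.50 with no filter on dim probes. On the same arrays the plasma protein list stood at a median of -8.77 and the markers of other cultured lines at 2.83.

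Of 46 replication-dependent histone genes, whose messages mostly lack a poly(A) tail, 14 fell and 0 rose, the same numbers as adjusted over the list alone, and 23 fell with the block. H2AC6 fell by 6.87 ± 0.58, H2BC12 fell by 4.06 ± 0.51 and H1-5 fell by 5.98 ± 0.87, and H1-1 was at least 56.5-fold lower. Histone genes share sequence, and the probes of H2AC6 disagreed in direction. The median was -1.39, with -1.86 on slide 1 and -1.15 on slide 2 (camera, adjusted p = 1.57e-04, and adjusted p = 0.901 with an estimated correlation). The call ended without Huh7.5 replicate 1, where the median was -0.55 (adjusted p = 0.136, against 3.09e-11 to 0.136 over its 13 alternatives). The median was -2.32 without Huh7.5M replicate 1, -2.55 without Huh7.5 replicate 2 and -0.86 without Huh7.5M replicate 2. Genes of the translation machinery had smaller differences. Of 78 cytosolic ribosomal protein genes, 0 passed in limma, over all genes and adjusted over the list alone, and 1 fell at an unadjusted p under 0.05. That gene, RPL6 (-1.87 ± 0.50, adjusted p = 0.0545), passed with normexp (-1.97, adjusted p = 0.0295), with the replicate block (adjusted p = 0.0156) and with a trend and robust prior (adjusted p = 0.0268). The ribosomal median of -0.57 (-0.54 on slide 1 and -0.51 on slide 2) was called lower by camera (adjusted p = 0.0151, and adjusted p = 0.548 with an estimated correlation). That median turned to 0.42 under spike-in scaling (adjusted p = 0.355). Over its 13 alternatives the adjusted p went from 0.00313 to 0.988, and the call also ended with quantile scaling, without Huh7.5 replicate 1 (0.231) and without Huh7.5M replicate 2 (0.311). Of 48 translation factors 0 passed in limma, over all genes and adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05, and 3 rose and 1 fell with the replicate block (median -0.40, turning to 0.07 under quantile and 0.59 under spike-in scaling, camera adjusted p = 0.444). The housekeeping genes ACTB and GAPDH differed by -1.48 ± 0.51 (adjusted p = 0.105) and -1.02 ± 0.69 (adjusted p = 0.374), and ACTB passed with the replicate block (adjusted p = 0.0373). All these genes were read on arrays where the plasma protein median was -8.77 and that of the markers of other cultured lines was 2.83.

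**Figure D3:**
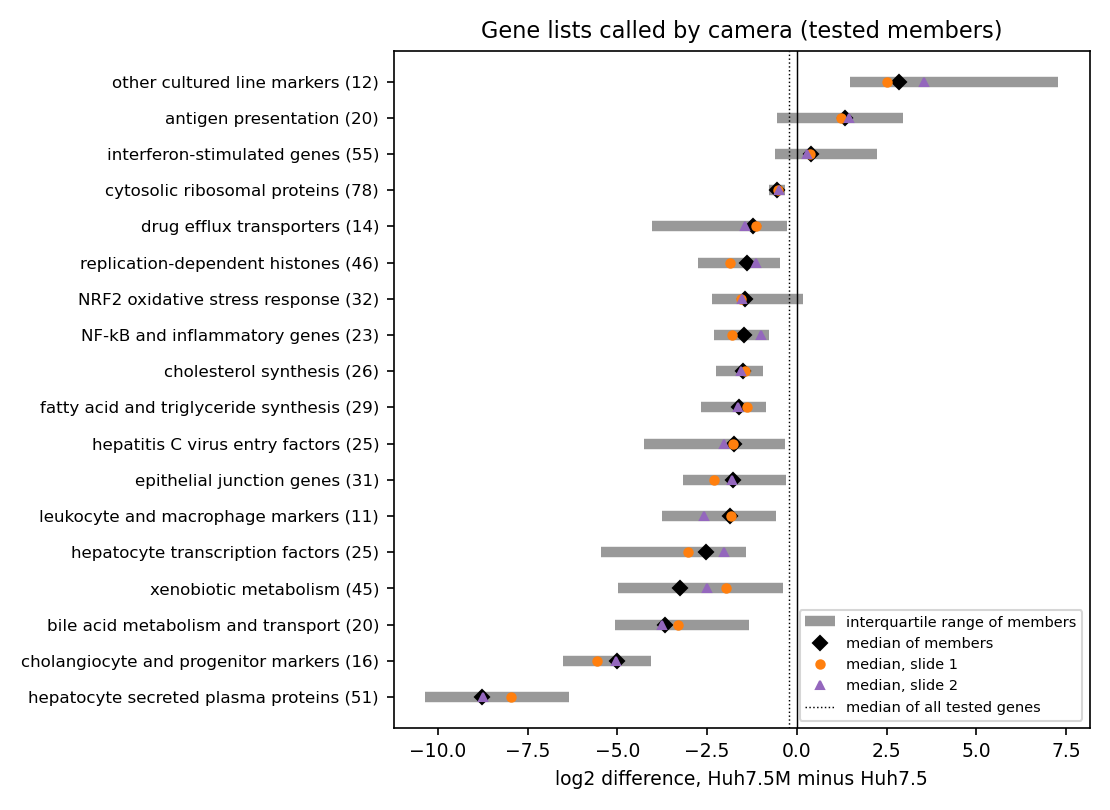
The 18 gene lists called by camera, with the log2 difference of their tested members on the x axis (Huh7.5M minus Huh7.5); grey bars span the interquartile range, diamonds are medians, and circles and triangles are the medians on slides 1 and 2. Medians run from -8.77 for secreted plasma proteins to 2.83 for markers of other cultured lines, and the dotted line marks the median of all tested genes (-0.21); under spike-in scaling the ribosomal protein median lies at 0.42.

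Of 37 tested lists, camera called 18 with the preset correlation, 3 higher and 15 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.375. That value also went to hepatocyte transcription factors, whose estimated correlation was -0.0365. Estimates were also under the preset of 0.01 for xenobiotic metabolism, entry factors, leukocyte markers and the NRF2 response. They were above it for the other called lists, among them plasma proteins (0.129), cholesterol synthesis (0.366) and, highest, histones (0.863). Camera's p-values at the preset may be too small for those lists. With so few arrays the setting with an estimated correlation had little power, so its 0 counts neither for nor against the 18 lists. With the replicate block for the slide, limma called 7161 genes, 3463 higher and 3698 lower, and camera called 18 lists, the same 18. Of all 21982 tested genes, 3515 were at least 2-fold higher and 3830 at least 2-fold lower on both slides. The groups did not overlap for 59.8% of tested genes, where chance gives 33.3% if the 4 arrays are exchangeable. Same-numbered arrays share a slide, so that value does not strictly hold here. The spike-in signal moved more between slides than between lines, so scaling on it does not establish a general rise in Huh7.5M. Scaled on the spike-in controls with the replicate block, an alternative chosen after seeing the data, 81.5% of 8902 called genes were higher. The share was 48.4% of 7161 with the block alone and 54.4% of 3948 without it. With the spike-in scaling, the median of all tested genes lay at 0.78 in place of -0.21. Lists stayed called as lower with smaller medians, among them hepatocyte transcription factors (-1.54), leukocyte markers (-0.88), junction genes (-0.80), entry factors (-0.77), fatty acid synthesis (-0.64), cholesterol synthesis (-0.53), NF-kB genes (-0.47), the NRF2 response (-0.47), histones (-0.41) and drug efflux (-0.22).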

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

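Most counts stayed within 1.5 times of 3948 genes and 18 lists. Requiring a signal well above background on all 4 arrays left 1225 genes and also left fewer than 5 members of the other-line and leukocyte lists, which were then not tested. With the replicate block, 7161 genes were called, all 3948 among them. Spike-in scaling with the replicate block, chosen after seeing the data, called 8902 genes (7253 higher, 1649 lower), 3646 of them among the 3948, and turned the median of 16 lists, 1 of them called; the cause was not tested. Camera with an estimated correlation, which had little power on 4 arrays, called 0 lists (37 tested, limma). Fry, which does not compare a list with other genes, called 11, of which 10 were among the 18. Leaving out 1 array gave 3135 to 3864 genes and 17 to 19 lists, with the lone array of a line assumed to vary like the others. Same-numbered arrays share a slide, and the numbers are not otherwise known to pair cultures. The block changed no list call. Neither a list nor any of 177 named genes turned a called direction under the alternatives run. The remaining counts ran from 2848 genes (normexp) to 4202 (mean of a gene's probes). Of the 139 called named genes, normexp ended the call of 10, the most among settings that left out no array and tested the gene. The filter on all 4 arrays left many of the 177 named genes untested. There 73 kept their result and 8 lost their call. Signal over background limits the folds: 786 genes called lower had a main probe that was not well above background on either Huh7.5M array. Without Huh7.5M replicate 2 the count was 3864 and without Huh7.5 replicate 2 it was 3135.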

Other observations

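Several lists that camera did not call held strong movers in both directions. Of 38 genes of glycolysis and hypoxia, 4 rose and 4 fell, the same numbers as adjusted over the list alone (median -0.40, adjusted p = 0.845). The glycolytic enzymes PFKP and HK1 were at least 922-fold and 127-fold higher in Huh7.5M, while SLC16A3, a lactate exporter, fell by 9.48 ± 0.48. Of 28 innate sensing genes, 4 rose and 3 fell, also adjusted over the list alone (median -0.04, adjusted p = 0.845). STING1, the adaptor of cytosolic DNA sensing, rose by 6.29 ± 0.46 and TICAM1, an adaptor of double-stranded RNA sensing, was at least 359-fold lower. Of 30 p53 targets, 3 rose and 3 fell, also adjusted over the list alone (median 0.42, adjusted p = 0.161). PHLDA3 and FAS rose by 5.64 ± 0.55 and 5.13 ± 0.52, and GDF15, a stress cytokine, fell by 4.42 ± 0.59. Of 31 apoptosis regulators, 2 rose and 3 fell, also adjusted over the list alone (median -0.30, adjusted p = 0.845). CASP4, an inflammatory caspase, fell by 8.41 ± 0.51, and HRK, whose probes disagreed in direction, rose by 5.52 ± 0.65. Of 30 immediate early genes, 5 rose and 4 fell, or 5 and 7 adjusted over the list alone (median 0.12, mean -0.15, adjusted p = 0.831). DUSP6, a phosphatase induced by ERK signalling, fell by 7.21 ± 0.55. Of 22 nuclear and non-coding RNAs, 1 rose and 2 fell, also adjusted over the list alone (median -0.50, adjusted p = 0.261). That list was called lower without Huh7.5 replicate 2 (-1.13, adjusted p = 0.0207). HULC, a liver non-coding RNA, fell by 8.78 ± 0.94. Of 39 lysosome and autophagy genes, 1 rose and 2 fell, or 1 and 1 adjusted over the list alone (median -0.48, adjusted p = 0.0676). It was called lower in 3 of 13 alternatives: normexp (adjusted p = 0.0460), a signal well above background on all 4 arrays (0.0267) and without Huh7.5 replicate 1 (0.0423). CTSZ was at least 266-fold lower and LAMP3 at least 38.0-fold higher. With the replicate block, the numbers that rose and fell were 5 and 7 (glycolysis and hypoxia), 6 and 6 (innate sensing), 5 and 5 (p53 targets), 6 and 5 (apoptosis), 7 and 7 (immediate early genes), 1 and 5 (nuclear and non-coding RNAs) and 1 and 11 (lysosome and autophagy).

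Markers of stellate and endothelial cells gave no common direction. Of 13 stellate cell and fibroblast markers, 3 rose and 4 fell, or 3 and 5 adjusted over the list alone (adjusted p = 0.845). Their median was 0.15 while their mean was -0.87 and the test pointed down. RELN was at least 54.9-fold lower, and COL1A1 was at least 20.0-fold higher, although another of its probes was well above background on 1 Huh7.5 array. Of 5 endothelial markers, 1 rose and 1 fell, also adjusted over the list alone (median -0.78, adjusted p = 0.670). Core cellular functions had few called genes. In the lists for oxidative phosphorylation (69 genes, median -0.36, adjusted p = 0.330) and aminoacyl-tRNA synthetases (23 genes, median -0.14, adjusted p = 0.845), limma called 0. At an unadjusted p under 0.05, 2 of the former were lower and 1 of the latter was higher. With the replicate block these passed: NDUFV1 (-1.46, adjusted p = 0.0289) and NDUFV2 (-1.27, adjusted p = 0.0470) as lower, and SARS1 (1.96, adjusted p = 0.0119) as higher, which was called in 6 of 14 alternatives. Of 65 mitochondrial ribosome genes, 1 fell (median -0.13, adjusted p = 0.845), and of 56 cell cycle genes, 1 fell (median -0.63, adjusted p = 0.261), with 0 in each adjusted over the list alone. With the block, the numbers that rose and fell were 2 and 9 (cell cycle), 1 and 1 (mitochondrial ribosome), 1 and 4 (heat shock), 1 and 8 (unfolded protein response) and 6 and 3 (ATF4 response). Of 32 heat shock genes, 1 fell, also adjusted over the list alone (median -0.65, adjusted p = 0.116). That gene was HSPA1A (-7.99 ± 1.42), whose probes disagreed in direction: its call ended with the mean of its probes (-2.70, adjusted p = 0.210) and on the probe well above background on all 4 arrays (-0.22, adjusted p = 0.924). Without Huh7.5M replicate 2, camera called the heat shock list (-1.17, adjusted p = 0.00721) and the cell cycle list (-1.08, adjusted p = 0.0325) lower. Of 32 genes of the unfolded protein response, 1 rose and 2 fell, or 1 and 0 adjusted over the list alone (median -0.47, adjusted p = 0.216). Of 32 genes of the ATF4 response, 1 rose and 2 fell, or 0 and 1 adjusted over the list alone (median 0.00, with the test pointing up, adjusted p = 0.845). Under spike-in scaling, the medians of all lists in this part that lay below 0 came to lie above 0, and with quantile scaling those of oxidative phosphorylation (0.11), the synthetases (0.11), the apoptosis regulators (0.14), the ATF4 response (0.18) and the mitochondrial ribosome (0.26) did so too. The medians of the ATF4 response and innate sensing also turned with median centring (0.06 and 0.03) and normexp (0.09 and 0.02), and that of the stellate cell markers with normexp (-0.09).

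The tests below on RNA of another line, on dilution, on scaling, on cell state and on a trace were chosen after the result was seen, while the spike-in test and the tests on replicate spots were fixed before their values were seen, with the test on the raw signal added after that on the processed signal. The pattern that most calls for follow-up is the near absence of hepatocyte messages from both Huh7.5M arrays, in a culture described as hepatoma. The scaling between arrays is argued against, since the plasma protein median fell by 6.30 or more under each of 6 scalings and background corrections. The median plasma protein gene kept 0.399% of its Huh7.5 level on slide 1 and 0.233% on slide 2, with upper quartiles of 1.25% and 1.12%. These shares argue against a culture that still held a sizeable part of Huh7.5 cells. Overgrowth that left almost none of them cannot be told from RNA of another line. RNA of another cultured line in place of the hepatoma line stays open as a hypothesis: 7 of 12 markers of HEK293 and HeLa type cells were called higher (9 adjusted over the list alone), among them CDKN2A (6.60 in Huh7.5M against 4.55 in Huh7.5), NEFL (2.60 against -7.17) and SOX2 (1.60 against -5.48), although 5 of the 12 were well above background on both Huh7.5 arrays. A test for adenovirus E1A, which HEK293 cells carry, decided nothing: the E1A control probes differed by -0.62, but all 10 formed a graded series spanning 3.64 to 4.32 log10 units on each of the 4 arrays, so they read transcripts added to every sample and the expectation written for this test was wrong. A change of cell state within the hepatoma line also cannot be told apart. The mesenchymal list, the only one used to test it, went both ways around a median of 0.064, and other kinds of state change were not tested. The resistance to geneticin given by the labels does not separate these explanations. An exchange of the lines' labels on both slides was not tested.

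Replicate spots of a probe varied more on slide 2 than on slide 1. Lower signal is argued against, because the median coefficient of variation of replicated probes at matched brightness was 5.86 times (Huh7.5) and 6.28 times (Huh7.5M) that of slide 1. In the processed signal, where this excess was measured, a quadratic surface accounted for at most 2.93% of the variance of replicate spots on slide 2. On slide 1 it accounted for 4.06% and 3.94%. A gradient of that shape left in these detrended values is thus argued against as the source of their excess. A gradient before detrending cannot be told apart. In the raw signal the surface accounted for 40.9% and 44.2% on slide 2, between the bounds set for this test, and for 64.2% and 49.2% on slide 1. These are shares of unequal variances. The raw median coefficient of variation at matched brightness was 25% and 31.8% on slide 2 against 6.55% and 5.64% on slide 1. No biological explanation was tested, and the source of the noise stays open.

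A faint signal of plasma protein genes remained on the Huh7.5M array of slide 1. If it came from a constant trace of Huh7.5 RNA, bright genes would keep a similar share. There were 17 plasma protein genes with a Huh7.5 mean above 4 that were well above background on the slide 1 Huh7.5M array. This filter can leave out the deepest falls. The log2 ratios of these 17 genes had an interquartile range of 1.13 around a median of -9.86 (0.108% kept). For 209 other bright genes called lower the range was 2.41 around -3.13. That set mixes falls of all sizes, so its wider range is no test of a trace. For the 13 brightest, which were all the list's genes of that brightness, the range was 1.34 around -9.91. On slide 2, some of the same 17 genes lay at background. APOA1 stood at -6.85 on the Huh7.5M array, where the lowest signal well above background was -5.31. With that limit, the 17 genes had a median of -11.1 on slide 2, a share of 0.0455%, with a wider interquartile range of 1.50. A trace of this size, from handling or hybridisation, is a candidate explanation, and low expression in the cells themselves was not excluded. A narrow range cannot tell a trace from similarly low expression of these genes. Whether the faint signal followed the Huh7.5 level was not tested.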
